A study of Homo sapiens with 3 samples.

How the data were processed

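Cells of the established human pancreatic cancer line BxPC-3 were grown for 48 h in a saturating nutrient medium, in a medium labelled Glc- or in a medium labelled Gln-, per the labels. The labels neither spell out the abbreviations nor give concentrations; they are taken here to mean poor in glucose and in glutamine. RNA from each culture was hybridized to 1 array, so the series holds 3 arrays and 1 array per medium. Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was copied by random priming along the whole transcript, and the product was labelled with 1 dye. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.0.1.1.

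The deposited scanner tables give each spot's processed signal as an intensity on a linear scale, per the file headers; they also give the median intensity of the spot and of its local background. The tables carry flags per spot, deposited by the authors as 0 or 1 values, for being well above background, saturated or an outlier. The authors also deposited a table of log2 values for 61024 probes. How those log2 values were made is not given in the sources used here. Their medians were 3.57 for each of the 3 arrays, and 20492 probes of the saturating medium, 24949 of Glc- and 25832 of Gln- medium sat at their column's lowest value. Their rank correlation with the same array's processed signal was 0.987, 0.965 and 0.961 in that order, so they follow the arrays' direction, and their exact normalization and floor remain unknown.

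Each array held 62903 spots, among them 60904 vendor probes with 1 spot each, 20 probes with an RNA accession and 10 spots each, 360 negative-control spots and other controls. The accessions were paired with gene symbols through a RefSeq gene table of assembly GRCh38.p14, without version numbers, and all 20 matched. The files and that table do not pair the vendor probes with genes. The vendor probes are therefore unnamed here, and whether one measures a long non-coding RNA or an mRNA is not known from these sources. No genome positions are printed, since the array design and the gene table rest on different assemblies.

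The main values were log2 of the processed signal minus each array's 75th percentile over all vendor and accession probes. Spots marked as outliers were left out of the array concerned, and no spot was saturated. Probes were counted when they differed by 2-fold or more between a pair of arrays and were well above background on at least 1 of them. With 1 array per medium there is no replicate spread and no p-value. Each difference compares these arrays, and the number of arrays limits the precision. The SD over the 10 spots of an accession probe measures the spread within an array only, and is taken over the differences between spots at the same position on the arrays compared. A probe well above background on 1 array of a pair has a bound in place of a fold: the brighter value against the higher of the dim array's lowest well-above-background signal and the probe's own signal.

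The main comparisons, the gene lists, the rule for naming and the alternatives, other than those named below as added, were set before the data were examined. By that rule a gene or probe could be named when its signal was well above background on both arrays, carried no outlier mark on either, and, as a mean over the 3 arrays, lay above the median (0.14 on the normalized log2 scale) of the probes detected on all 3 arrays. For accession probes, single outlier-marked spots were left out and the remaining spots averaged. With no class annotation, the 12 largest rises and 12 largest falls were to be named. Only accession genes have names, so these are reported, except for 2 whose values are not reported here though they enter the counts and medians over the 19 genes detected on every spot, and of the unnamed probes at most 2 that were higher and 2 that were lower are given by their vendor number. Of 44 gene lists fixed in advance with 895 genes, only 5 have a member among the accession genes detected on every spot, and no more than 5 members were measured in any. The planned comparison of list medians with 10000 random lists was therefore not run. The planned background correction used a mean spot signal that the files used here do not carry, and was run on the median spot signal in its place (limma 3.58.1, normexp with an offset of 50, then quantile normalization).

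Bright and dim areas were marked after the data had been seen. A spot was marked on an array when at least 25 percent of the neighbouring probe spots within 30 position units, with at least 10 neighbours, were higher, or lower, there than on both other arrays by 1.5 or more on the log2 scale. The spot's own value did not enter. This setting was chosen from 5 tried because it marked the fewest spots after positions were shuffled, 128 in all against 1218 with the true positions. Under the other 4 settings the number of bright spots on the Gln- array lay between 971 and 1253.

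The steps were tested on simulated data built from the saturating array, with 200 probes changed and a bright disc added to the array that stood for Gln-. Over 61104 spots, all 103 probes changed by 1.5 on the log2 scale outside the disc were recovered at 2-fold or more, as were all 91 changed by 2. Of 36001 unchanged detected probes outside the disc, 234 passed 2-fold. All 544 spots inside the disc were marked, along with 89 spots outside it. The changed probes were drawn from the brighter detected probes, and the noise added was smaller than the spread between the real arrays. That spread, which includes any effect of the media, had SDs of 0.49 to 0.75 for bright probes outside marked areas. Full recovery was thus largely built in and does not measure sensitivity on the real arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.

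The alternatives were quantile normalization, scaling to the median, scaling to the 75th percentile of the probes detected on all 3 arrays, normexp, the deposited log2 values, other filters on dim probes and a 1.5-fold threshold. Normexp on the median signal in place of the mean, keeping the outlier-marked spots and leaving out the marked areas were added after the data had been seen. Per the file headers, the arrays of Glc- and Gln- medium shared a scan (scan 2) and the saturating array came from another (scan 1). Scan and medium therefore cannot be told apart in either comparison with the saturating medium, while Glc- and Gln- were compared within scan 2.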

Results

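RNA from BxPC-3 cells, an established human pancreatic cancer line, was measured on 3 single-colour arrays after 48 h in saturating nutrient medium, Glc- medium or Gln- medium. The saturating array was the brightest. The 75th percentile of its processed signal was 147.6, against 85.6 for Glc- and 76.7 for Gln-, a ratio of 1.72 and 1.92. Of 60904 vendor probes, 36314 (59.6%) were well above background on the saturating array, 31596 (51.9%) on the Glc- array and 30551 (50.2%) on the Gln- array. The same call was met by 18.3%, 12.5% and 10.6% of the 360 negative-control spots in that order, so a call close to background is weak evidence of a transcript. There were no replicate arrays. The SD given beside a gene is the spread over its spots on the arrays compared, at most 10 spots, and says nothing about another culture.

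The first comparison asked how the RNA of cells in Glc- medium differed from that in saturating medium. Among the accession-named genes, most of them widely used reference genes, several were higher on the Glc- array. ACTG1, which encodes cytoplasmic gamma-actin, was higher by 1.04 ± 0.05 (log2, SD over spots), or 2.06-fold. EIF3D, a subunit of a translation initiation factor, was higher by 1.03 ± 0.04, or 2.04-fold. RACK1, a scaffold protein of the ribosome's small subunit, was higher by 0.81 ± 0.03. The glycolytic enzyme gene PGK1 went the other way and was lower on the Glc- array, with a difference of -0.59 ± 0.07, or 1.51-fold. These directions held under all 5 other scalings, but ACTG1 and EIF3D reached 2-fold in only 1 of them, median scaling. Under the other 4, ACTG1 lay between 0.66 and 0.99 and EIF3D between 0.87 and 0.98, and RACK1 came down to 0.41 under quantile normalization. Against vendor probes of like brightness, ACTG1 lay at percentile 96.9, EIF3D at 94.5, RACK1 at 93.5 and PGK1 at 11.3.

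Among the 19 accession genes detected on every spot, PGK1 had the largest fall on the Glc- array. Its 2 human control probes gave -0.66 ± 0.03 and -0.74 ± 0.12, so all 3 probes for this gene had lower signals there. Against vendor probes of like brightness, the 2 control probes lay at percentiles 1.5 and 7.5. GAPDH, the other measured member of the list of glycolysis and lactate export (2 of 23 genes measured), differed by 0.17 ± 0.07, and its direction turned under quantile normalization, normexp and the deposited values, where it lay as low as -0.19. Its human control probes gave 0.11 ± 0.05 and 0.36 ± 0.05. Neither gene reached 2-fold. The 2 measured genes of 32 in the list of cytosolic ribosomal proteins, RPLP1 and RPS18, were higher by 0.48 ± 0.07 and 0.43 ± 0.06. Both stayed higher under every scaling run, at no less than 0.16 and 0.10. Against vendor probes of like brightness they lay at percentiles 81.5 and 77.4. ODC1, the first enzyme of polyamine synthesis and the measured member of the list of ribosome biogenesis and MYC targets (1 of 28 genes), was higher by 0.44 ± 0.05. COX4I1, a subunit of cytochrome c oxidase and the measured member of the respiratory chain list (1 of 26), was higher by 0.34 ± 0.04, or 0.08 at the lowest under the other scalings.

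The list of housekeeping genes had 5 of its 22 members measured. On the Glc- array ACTG1 was higher by 2-fold or more under the main scaling, and ACTB, GAPDH and PGK1 lay between 2-fold lower and 2-fold higher. The cytoplasmic actin genes parted: ACTB differed by only 0.16 ± 0.08, a direction that turned under 3 of the 5 other scalings, while ACTG1 was 2.06-fold higher. Among the remaining genes, PRMT1, an arginine methyltransferase gene, was higher by 0.46 ± 0.04 and MTX1, a mitochondrial import gene, by 0.29 ± 0.03. At the lowest, PRMT1 came to 0.30 under normexp and MTX1 to 0.13 under quantile normalization. RPL10 was also higher, by 0.45 ± 0.15, but from a signal below the brightness limit for naming. DYNLL1, H3-3A, PFN1 and ARHGDIA differed by between -0.04 and 0.13, and the direction of each turned under at least 1 scaling. In all, 17 of 19 genes detected on every spot were higher and 2 lower, with a median difference of 0.34. Under all 5 other scalings 12 stayed higher and 1 lower. Against vendor probes of like brightness, 2 of the 19 genes lay above percentile 95 and 0 below percentile 5. GRM4, a glutamate receptor gene, was well above background on only 3 of its 10 spots on the Glc- array and 4 on the Gln- array, and no difference is given for it.

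**Figure D1:**
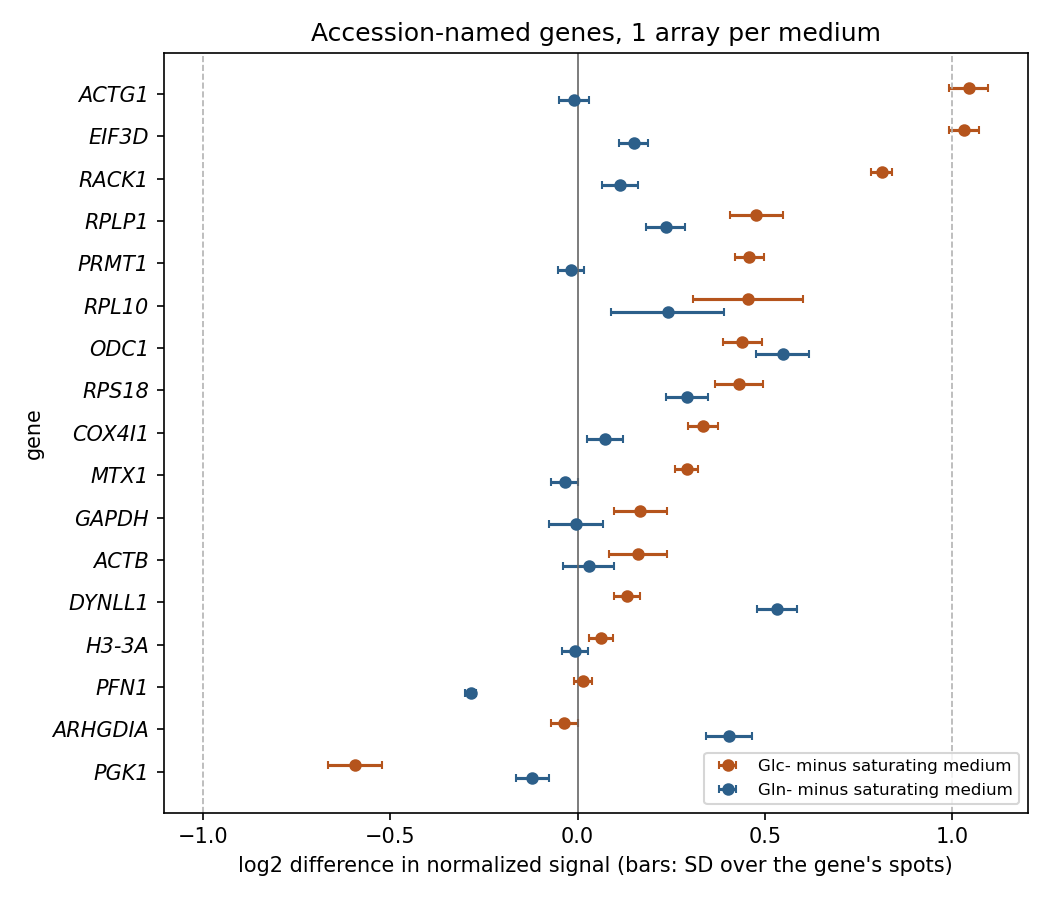
Differences in normalized log2 signal (horizontal axis) of 17 accession-named genes detected on every spot (vertical axis), on the Glc- array (orange) and the Gln- array (blue) against the saturating array; points are means over spots, bars are the SD over spots, and dashed lines mark 2-fold. ACTG1 and EIF3D lie at 1.04 and 1.03 on the Glc- array and PGK1 at -0.59, while none of these genes reaches 2-fold on the Gln- array; genes near 0 change side under other scalings.

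Across the vendor probes, 3167 of 36995 were 2-fold or more higher on the Glc- array than on the saturating array and 3025 were lower. The deposited values gave a different split, 3097 higher and 1898 lower, and normexp gave 725 and 296. The number of falls depended on the filter. Among the 30865 probes well above background on both arrays, 2478 were higher and 1044 lower. That filter removes falls in part by itself, since a probe that falls on the dimmer array can lose the call. Of 5425 probes detected on the saturating array only, the bound reached 2-fold for 224, and of 705 detected on the Glc- array only, for 560. That contrast comes in part from scaling, which places the detection level of the dimmer Glc- array higher. In the upper signal range fixed for naming, 1032 of 14408 probes were higher and 342 lower.

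The largest probe rise on the Glc- array that met the naming rule lay beside a dim area of the saturating array, where 13 of 38 neighbouring probes were also 2-fold or more higher, and it is not named. The next was ASHGV40040828, which was 130-fold higher than on the saturating array, with a processed signal of 6852 against 90.7, and had a signal of 36.2 on the Gln- array. The largest fall was that of ASHGV40037960, 52.5-fold lower, with a signal of 20.1 against 1823 on the saturating array and 787 on the Gln- array. For ASHGV40040828 and ASHGV40037960, normexp gave log2 differences of 6.11 and -4.03, against 7.03 and -5.71 under the main scaling. Both probes have 1 spot per array and their genes are not named in the files.

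The second comparison put Gln- medium against saturating medium. None of the 19 accession genes detected on every spot reached 2-fold in either direction. ODC1 was higher by 0.55 ± 0.07, or 1.46-fold, and DYNLL1, which encodes a dynein light chain, by 0.53 ± 0.05, or 1.45-fold. ARHGDIA was higher by 0.41 ± 0.06. PFN1, encoding the actin-binding protein profilin, was lower, with a difference of -0.29 ± 0.02. Under the other scalings PFN1 lay between -0.65 and -0.25. These 4 directions held under all 5 other scalings, with DYNLL1 at 0.21 and ARHGDIA at 0.13 at the lowest. Against vendor probes of like brightness, ODC1 lay at percentile 85.8, DYNLL1 at 69.5, ARHGDIA at 66.9 and PFN1 at 9.8. Differences of this size were thus not unusual for probes as bright.

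Of the genes named above as 1.75-fold or more higher on the Glc- array, ACTG1 differed by -0.01 ± 0.04 on the Gln- array, EIF3D by 0.15 ± 0.04 and RACK1 by 0.11 ± 0.05, and each changed sign under at least 1 other scaling. PGK1 differed by -0.12 ± 0.04, and its control probes by -0.19 ± 0.03 and -0.25 ± 0.12. The ribosomal protein genes RPS18 and RPLP1 differed by 0.29 ± 0.06 and 0.23 ± 0.05, and RPLP1 changed sign with the deposited values. Against vendor probes of like brightness they lay at percentiles 49.4 and 43.3, so these differences were ordinary for probes as bright. In total, 11 of the 19 genes were higher and 8 lower, with a median of 0.07, or -0.13 under quantile normalization and -0.20 with the deposited values, where 6 were higher. Against vendor probes of like brightness, the median percentile of the 19 genes was 35.4.

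Among vendor probes, 1681 of 36902 were 2-fold or more higher on the Gln- array and 3105 lower. Part of the rises lay in bright areas on the surface of that array, in which 969 spots were marked. Those areas held 371 of the 2-fold rises and 10 of the 2-fold falls among 732 compared probes, and 41.9% of the 639 rises of 4-fold or more. Bright areas were marked where neighbouring probes were higher, so this excess of rises, and its removal with the areas, is in part built in. Without the marked areas of both arrays, 1304 probes were higher and 3089 lower. Among probes well above background on both arrays the counts were 1022 higher and 825 lower, and 858 and 819 without the marked areas. In the upper signal range, 259 of 14392 probes were higher and 376 lower, or 227 and 372 without the marked areas, so the direction of the excess depended on the filter. Requiring detection on both arrays itself drops probes that fell below detection on the dimmer Gln- array. The deposited values gave 1763 higher and 1931 lower. Of 6469 probes detected on the saturating array only, the bound reached 2-fold for 209. For 657 detected on the Gln- array only it reached 2-fold in 655, or 442 outside the marked areas. That contrast comes in part from scaling, which places the detection level of the dimmer Gln- array higher.

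**Figure D2:**
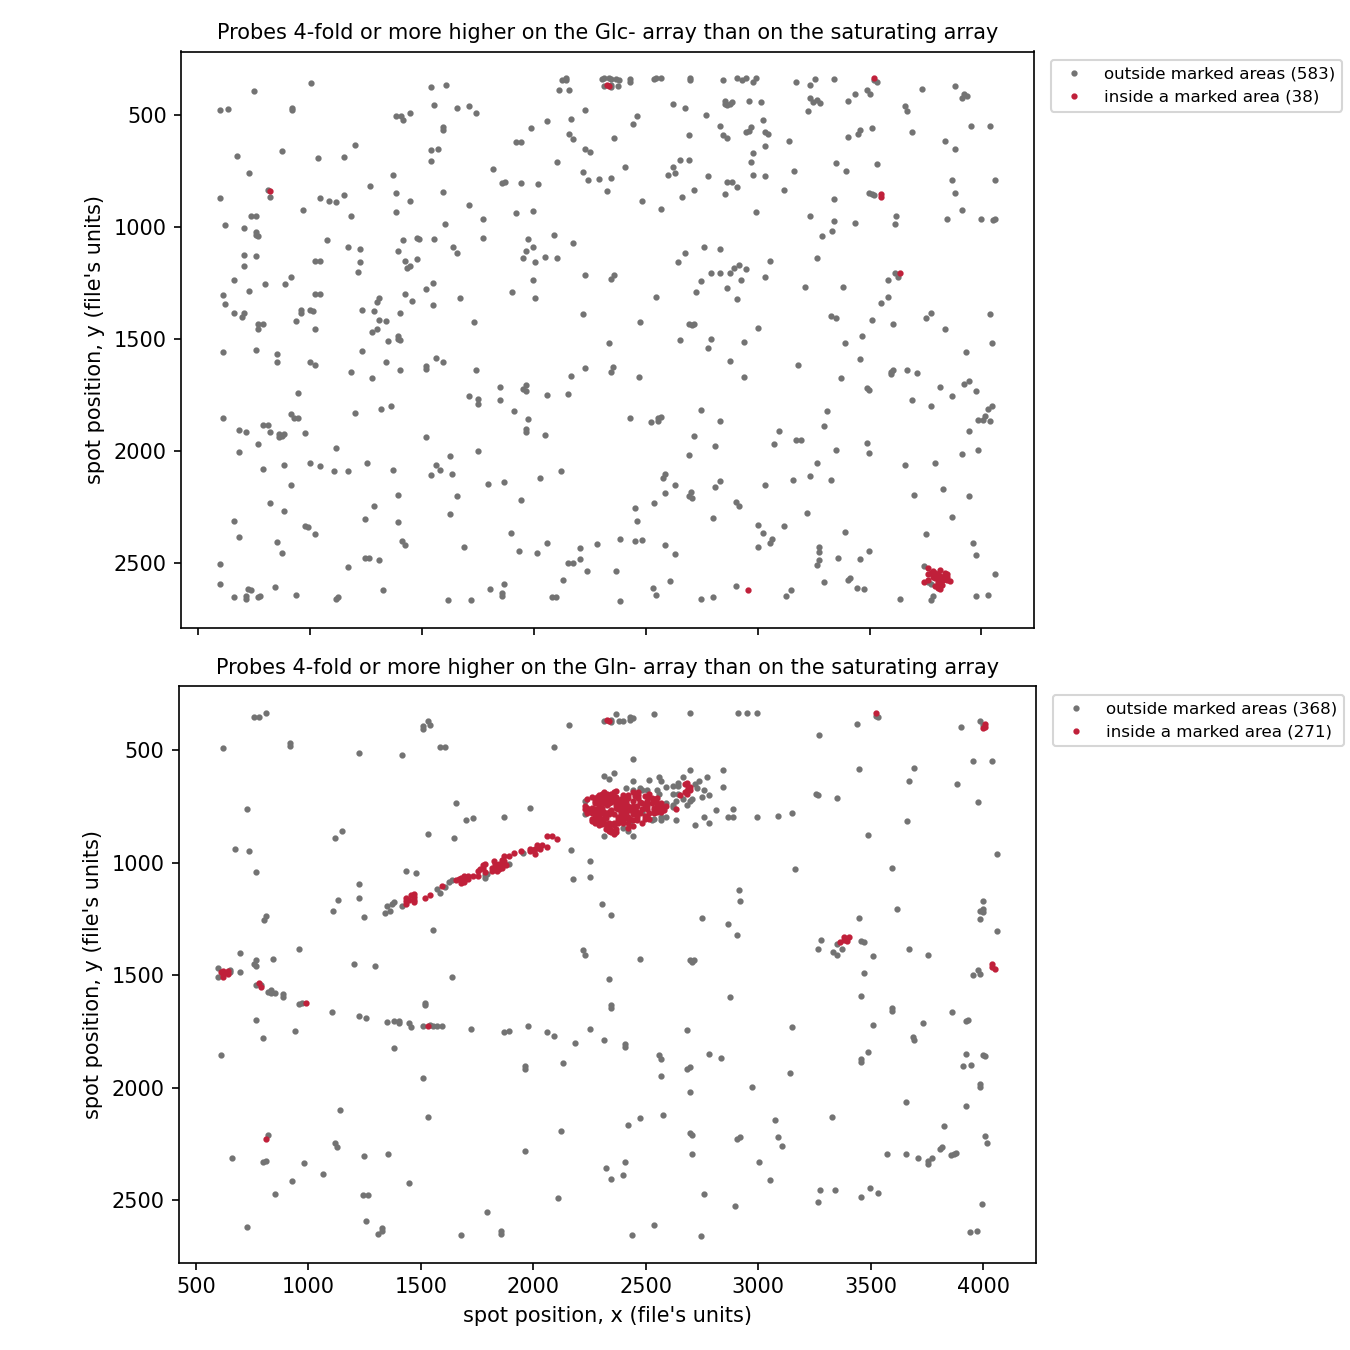
Positions on the array (horizontal and vertical axes, in the units of the scanner tables) of the vendor probes 4-fold or more higher on the Glc- array (upper panel) and on the Gln- array (lower panel) than on the saturating array; red points lie inside marked bright or dim areas of either array and grey points outside them. On the Gln- array 271 of 639 points fall inside marked areas, in a blotch and a streak, and unmarked points fringe the blotch and follow a thin arc; on the Glc- array 38 of 621 do.

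Of the 12 largest Gln- rises that met the naming rule, 6 lay inside marked areas. Outside them, and passing over the probe beside the dim area of the saturating array, the largest rise was that of ASHGV40007205, which was 30.4-fold higher, with a signal of 2924 against 187 on the saturating array and 89.6 on the Glc- array. None of its 49 compared neighbours was 2-fold higher. The largest fall was that of ASHGV40047381, 9.78-fold lower, with a signal of 22.1 against 420 on the saturating array. For ASHGV40007205 and ASHGV40047381, normexp gave log2 differences of 4.29 and -1.92, against 4.93 and -3.29 under the main scaling. The choice to pass over probes in or beside such areas was made after their values had been seen.

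The third comparison set Glc- against Gln- medium, within a single scan. ACTG1 was higher on the Glc- array by 1.05 ± 0.04, or 2.07-fold. EIF3D was higher by 0.88 ± 0.03, RACK1 by 0.70 ± 0.04 and PRMT1 by 0.48 ± 0.03. PGK1 was lower on the Glc- array, at -0.47 ± 0.08, as were ARHGDIA at -0.44 ± 0.07 and DYNLL1 at -0.40 ± 0.03. Against vendor probes of like brightness, ACTG1 lay at percentile 96.7, RACK1 at 92.1, EIF3D at 91.0 and PRMT1 at 78.9. PGK1, ARHGDIA and DYNLL1 lay at percentiles 21.2, 32.3 and 37.5. Differences such as those of PRMT1, PGK1, ARHGDIA and DYNLL1 were thus not unusual for probes as bright. For all 19 genes, 14 higher and 5 lower, the direction was the same under each of the 5 other scalings. These are not separate checks: median scaling and scaling on detected probes shift all genes alike, and normexp ends in quantile normalization. ACTG1 stayed at 2-fold or more in all but 1 of them, where it was 0.99. The human control probes for PGK1 differed by -0.47 ± 0.03 and -0.49 ± 0.16. GAPDH was higher by 0.17 ± 0.07, and by 0.24 ± 0.04 and 0.50 ± 0.06 at its human control probes. ACTB was higher by 0.13 ± 0.05. Sizes moved more than directions: under normexp GAPDH came to 0.0081 and ACTB to 0.022, and DYNLL1 came to -0.19 with the deposited values.

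Among vendor probes, 3877 of 33013 were 2-fold or more higher on the Glc- array than on the Gln- array and 2598 lower. Without the marked areas the counts were 3796 and 2193. In the upper signal range, 1561 of 14401 were higher and 785 lower, and the SD of the difference there, outside marked areas, was 0.75, against 0.63 for Glc- and 0.49 for Gln- relative to the saturating array. The array pair that shared a scan thus differed by no less than the pairs that did not. ASHGV40040828 was 168-fold higher on the Glc- array than on the Gln- array, and ASHGV40037960 was 44.0-fold lower. Under normexp their log2 differences came to 6.27 and -3.47, against 7.40 and -5.46 under the main scaling.

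**Figure D3:**
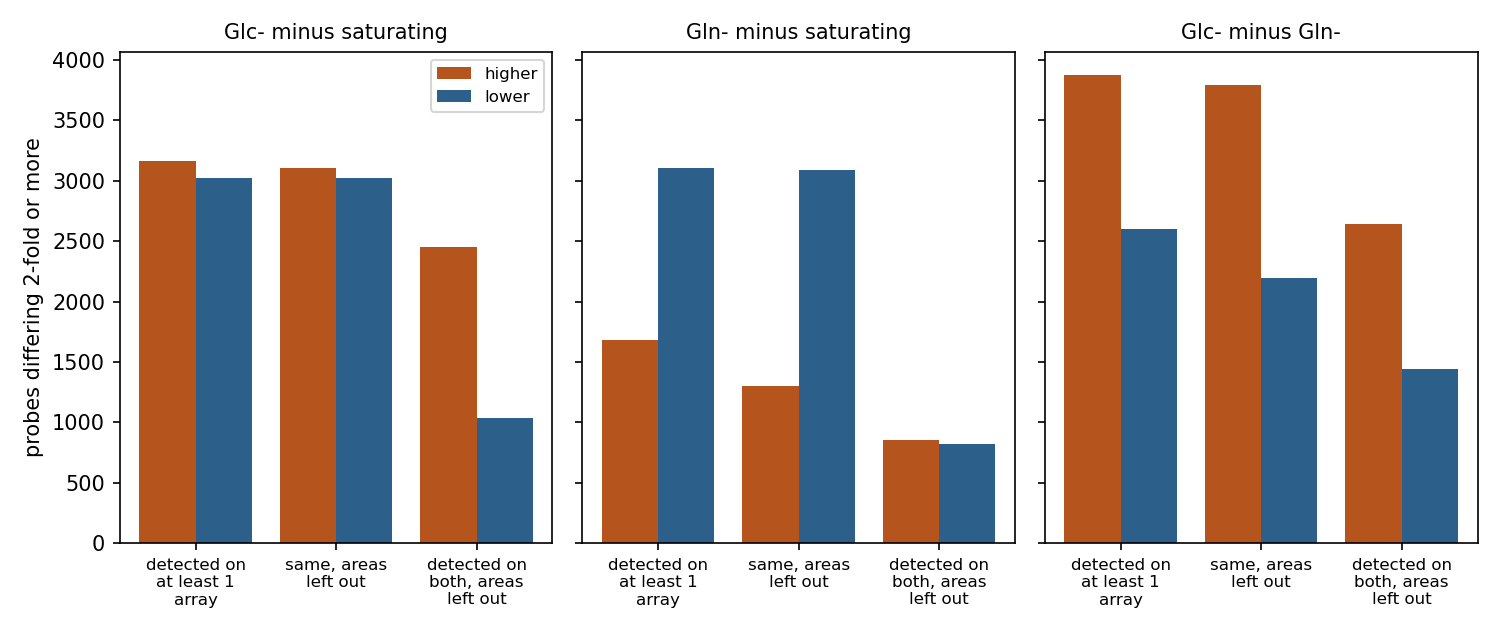
Numbers of vendor probes 2-fold or more higher (orange) and lower (blue) in each comparison (panels), counted over probes well above background on at least 1 array, the same without marked areas, and over probes well above background on both arrays without marked areas; the vertical axis starts at 0. The excess of lower probes on the Gln- array, 3089 against 1304, is absent among probes detected on both arrays, where 819 were lower and 858 higher. That filter itself drops probes that fell below detection on the dimmer array. In the upper signal range (not drawn) the excess is present, with 372 lower and 227 higher.

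Finally, 396 probes were 2-fold or more higher on both nutrient-poor arrays and 1241 lower on both, among 36415 probes compared in both. Opposite directions were met by 88 probes higher on Glc- and lower on Gln- and by 56 of the reverse. Independent lists of these sizes would share 87.2 higher and 258 lower probes. Both differences use the same saturating array, however. Unchanged media simulated with the spread between the Glc- and Gln- arrays shared 1028 higher and 1400 lower probes. The simulated noise kept the sign of Glc- minus Gln-, so its split into higher and lower depends on the order of subtraction. The 396 shared rises lay below both simulated counts, and the 1241 shared falls lay between them. The simulation therefore cannot say whether the shared falls exceed those of unchanged media. That simulation overstates the noise, since the spread between those arrays includes any effect of the media. Across the 28784 probes detected on all 3 arrays, which are not independent replicates, the differences correlated with r = 0.26. Their covariance was 0.092, against 0.294 in the simulation, a value set by the same overstated noise. With 1 saturating array the control could not be split, and part or all of the overlap may come from it.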

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

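The test of glutamine withdrawal, which reads the control spots, and the measure of clustering were chosen after the results were seen; the tests of a blemish and of brightness were set beforehand. In the bright areas of the Gln- array, negative-control spots and spots of the control probe 3xSLv1 stood above their level on the saturating array. Before scaling, the median log2 difference in processed signal over the 10 such spots was 3.01, with quartiles of 2.40 and 4.54. Also before scaling, spots of the same kind outside the areas differed by 0.09, and the same 10 spots differed by -0.0018 on the Glc- array.

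The largest rises on the Gln- array lay close together on its surface. Of the 4-fold rises, 20.7% had another as their nearest compared spot, against at most 4.38% in 1000 shuffles. Controls that target no transcript were brighter inside the areas than outside by 2.92, which a bright blemish requires and a change in the cells' RNA after glutamine withdrawal alone would not give. A blemish is thus a candidate explanation for the rises inside the areas, and a response of single probes there stays open. Outside the marked areas 8.70% of the 368 remaining rises still had a neighbouring rise, so the marking is likely incomplete. On the Glc- array the share over all 621 rises was 6.44%, against at most 3.86% when shuffled, and 4.07% over the 565 rises outside the marked areas of all 3 arrays.

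Both nutrient-poor arrays lost the well-above-background call more often than they gained it: 5430 probes lost and 712 gained on Glc-, and 6475 lost and 712 gained on Gln-. Dividing the saturating signals by the brightness ratio alone took 4450 probes below the Glc- array's detection level, 82.0% of the number lost, and 5286 below that of Gln-, 81.6%. Lower overall brightness may therefore account for most of the losses, and 62.7% and 67.1% of the lost probes were among those predicted. The scan and the medium are both open as sources of the lower brightness.

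After scaling, some control probes that enter no comparison were above the saturating array by over 3 times the combined SD of their spots. That SD is the root of the summed squares of both arrays' SDs. Every spot of these probes was well above background on both arrays. On the Gln- array these were the control probes (+)E1A_r60_a22, higher by 0.79 on the normalized log2 scale, and ERCC-00062_278, higher by 0.67. Before scaling, their median processed signals were lower on the Gln- array, at 63.0 against 70.2 and 7504 against 8993. On the Glc- array they were the control probes named Mouse-GAPDH_3, higher by 0.40, and Rat-GAPDH_5, higher by 0.26. Before scaling these were lower too, at 323 against 420 and 5175 against 7459. The rule listed rises only. The probes Mouse-GAPDH_5 and Rat-GAPDH_3 went the other way on the Glc- array, at -0.36 and -0.09.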

How the results depend on the processing

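Leaving out marked areas, keeping outlier-marked spots and normexp on the median signal were chosen after the data had been seen. Quantile normalization, median scaling, scaling on probes detected on all 3 arrays, keeping outlier-marked spots and leaving out marked areas left every count within 1.5 times. The larger moves follow, as higher and lower. Except where the filter or threshold sets the number, or the normexp offset shrinks folds, the cause was not tested. A 1.5-fold threshold gave 6420 and 7608 for Glc- against saturating medium, 4308 and 6705 for Gln-, 7370 and 6539 for Glc- against Gln-, and 1064 and 3119 in both media. The upper signal range gave 1032 and 342, 259 and 376, 1561 and 785, and 30 and 112 in that order. Normexp gave 725 and 296, 244 and 314, 1217 and 638, and 9 and 108. Its offset of 50 draws the folds of dim probes towards no change by construction. The median processed signals were 18.4, 10.4 and 9.30 on the saturating, Glc- and Gln- arrays. How much of the fall in counts the offset accounts for was not tested.

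Requiring detection on all arrays compared gave 1044 lower for Glc-, 1022 higher and 825 lower for Gln-, 1601 lower for Glc- against Gln-, and 222 and 280 in both media. Without a filter on dim probes 5653 were higher for Glc-, 14939 higher for Gln-, 4385 lower for Glc- against Gln- and 2157 higher in both. The deposited values gave 1898 lower for Glc-, 1931 lower for Gln- and 706 lower in both.

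Over 81 differences of named genes and probes, the sign changed for 9 under quantile normalization, 9 under normexp, 9 with the deposited values, 5 under median scaling and 4 under scaling on detected probes, the largest of them 0.23 in size under the main scaling. The planned comparison of list medians with random lists, and the median over several probes of a gene, were not run, for want of gene names.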

Other observations

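The test of consecutive numbers was set before its result was seen; both tests on the named genes were chosen afterwards. Vendor probes carry running numbers, and a pair among the largest Glc- rises outside marked areas had consecutive numbers and lay 37.4-fold and 37.2-fold above the saturating array. Over 4089 pairs of bright probes with consecutive numbers, the Glc- differences correlated with r = 0.12, above the highest of 1000 shuffled pairings, 0.06. Of 385 pairs whose first probe differed by 2-fold or more, the second did so in the same direction in 10.1%, against 5.58% if the members were unrelated. Neighbouring numbers may thus include probes for related transcripts, as a hypothesis, for a small part of the pairs. Glc- against Gln- gave r = 0.14 and Gln- against saturating medium 0.05.

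Of the 19 accession genes detected on every spot, 17 were higher on the Glc- array. Draws of 1 vendor probe of like brightness per gene reached the genes' median of 0.34 in 3.4% of 1000 draws, and the drawn medians centred on 0.10. A trend with brightness could thus supply part of the difference, and whether it supplies all of it is open. The choice of scaling is open too: the lowest median under the other scalings was 0.13, under quantile normalization, with 12 of the genes higher. The directions of ACTG1, EIF3D, RACK1 and PGK1 did not depend on the scalings run. A response of these genes to Glc- medium was not tested, for lack of replicate arrays.

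The control probe ETG09_35454 had a median signal of 40.5 on the saturating array, against 4.01 on Glc- and 3.72 on Gln-, where none of its 12 spots was well above background. The probes Mouse-PGK1_3, Mouse-PGK1_5 and Rat-PGK1_5 differed from the saturating array by -1.16, -0.99 and -0.92 on the Glc- array and, on the Gln- array, by -0.55, -0.56 and -0.45.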
